A study of Oryza sativa Indica Group with 2 samples.

How the data were processed

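Messenger RNA from rice leaves was measured in 2 libraries, 1 from a cold-tolerant and 1 from a cold-sensitive indica genotype, both after 6 h at 10 °C. Per the labels' protocols, poly-A RNA was copied with a poly-T primer, inserts were about 500 bp long, and single-end reads of 100 bp were made on an Illumina HiSeq 2000. The submitters' processing notes name Bowtie 0.12.7, a short-read aligner, and edgeR, a package for count comparisons. The genome build, the annotation release, the treatment of reads with several matches, the use of strand and the dispersion setting are not given in the sources used here. Reads of the 2 genotypes may thus have aligned to the reference unequally, and no ratio was checked for that.

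The values come from 1 table of the authors' own comparison, with 5804 coding-sequence models of 3946 rice loci. Per the file headers, the authors deposited 2 columns on a log2 scale, the mean log2 share of reads over both libraries and the log2 fold change between them. Each model also has a p-value and an adjusted p-value in the authors' deposited table. The largest adjusted p was 0.0499, so the table holds only models under an adjusted p of 0.05, and it holds none of the models that missed that limit. The relation of p to adjusted p gives 67393 models tested by the authors, of which 8.61% are in the table. Neither the header nor the labels tie the sign of the fold change to a genotype. The numerator is therefore called library A and the denominator library B, and neither was assigned to a genotype from its values.

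Reads were recovered from the log2 columns. Solving the log2 mean and the log2 fold change for each library's own share of reads gave values that were multiples of 1 fixed step per library, with 100% of values whole within 1e-06 of a read in both. The steps correspond to library sizes of 12846997 reads for A and 12152372 for B, which were not whole numbers and so are scaled sizes. Levels are in RPM, the reads of a model scaled by these sizes. Where a locus had several models, the model with most reads stands for it. That choice was made after the table had been seen. Of 1080 loci with more than 1 model, 298 had identical reads in all of them, and no locus had models of differing direction.

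With 1 library per genotype there is no replicate check, and no test of a difference between the genotypes was run. Comparisons with random lists, shuffles and redraws of loci describe these libraries only. The design fixed beforehand foresaw this, and since the deposited units were log2 values and p-values, no count model was fitted. Intervals are 95% exact intervals, Poisson for a level and Clopper-Pearson for a ratio of reads. They cover counting error only and leave out the spread between plants, for which there is no replicate. Reads copied by PCR or counted at several copies are not independent, so the intervals may be too narrow even for counting error. A library with 0 reads was given a floor of 3 reads, and a fold against it is the lower limit of the other level over that floor, rounded down. For 5732 models with a p large enough to compare, 92.2% of the authors' p-values lay within 1.5 times of an exact two-sided binomial p from the recovered reads, with a median ratio of 1.08, so the authors' p-values also cover little beyond counting error.

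Gene lists by identifier were fixed before the data were examined, with 33 genes in 5 lists: cold regulators, osmolyte and dehydrin genes, fatty acid desaturases, cellulose synthases and clock genes. A list of 10 photosynthesis and photorespiration genes was added after the values of the most abundant loci had been seen. The named genes are all list members found in the table and the loci with most reads among those read in 1 library, of which the first 2 per library are given. The parts of the rule that needed gene descriptions, the lists by description keyword and the alternative without transposons were not run, since the table used here pairs no locus with a name. The names paired with locus identifiers come from field knowledge. They were checked by position against the RefSeq gene table of assembly ASM3414082v1: 35 of 43 names were found there, all on the same chromosome and within 10% of its length of the place the locus number gives, with a largest difference of 7.75%. Random symbols passed that check in 2.16% of draws. The check covers the region of a chromosome and cannot tell neighbouring genes apart, such as OsDREB1A and OsDREB1B. The other 8 names, among them SNAC1, OsFAD7, OsFAD8 and OsFAD2, were not matched by symbol and rest on field knowledge alone.

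A list's median log2 ratio was set against 10000 random lists of the same size drawn from the loci of the table, matched in 10 classes of mean level. Alternatives were fold thresholds, p limits, a level filter, centring on the table's median, scaling to the table's own totals, pseudocounts of 1 and 0.1 RPM, unmatched random lists, and a limit of 3 reads in place of 0. One model per locus, the removal of loci with matching read pairs, and the table's own totals for lists and genes were added after the data had been seen. Centring moved all log2 ratios by 0.30 and the table's totals moved them by 0.20 towards A. Runs of loci read in 1 library were defined, after looking at gaps of several sizes, as at least 4 such loci with gaps of at most 2000 locus numbers. The tolerance of 1% for matching read pairs and the classes of level and ratio were likewise set after other tolerances and the distribution had been looked at.

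The steps were tested on simulated data with 3946 loci, of which 200 differed by known folds. Reads were recovered exactly for 100% of loci in both libraries. The interval held the simulated value for 100% of loci at a log2 ratio of -2, 97.9% at -1, 93.6% at 1 and 100% at 2. Random lists of 5 loci fell outside the middle 95% of percentiles in 5.5% of cases. By a share of shuffles under 0.05, the test for neighbouring loci found 2 planted runs of 12 loci (0.04 of shuffles as high). By that rule it did not find 1 such run (0.19), and 0 of 20 scattered sets passed. The rule used on the data is stricter, a count above all 10000 shuffles, and the 2 planted runs would not meet it. The test can thus miss a small number of runs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.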

Results

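Leaf transcriptomes of 2 indica rice breeding lines were compared after the same cold exposure. One line is described as cold-tolerant and the other as cold-sensitive, and their names in the labels share a stem. Seedlings about 20 days old, with 3 leaves, were kept at 10 °C for 6 h under 40 µmol m-2 s-1 of light, and the leaves of 9 plants went into a library. Each genotype had 1 library and no unchilled plants were sampled, so the comparison asks which genes differed between chilled leaves of the genotypes and cannot show which genes responded to cold. There were no replicates for any value. The authors' table does not say which genotype is the numerator of its fold change. The numerator is called library A, scaled to 12846997 reads, and the denominator library B, scaled to 12152372. Each ratio is a log2 ratio of A over B with its 95% counting interval, and positive values mean a higher level in A.

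The authors' deposited table held 3946 loci, with a median of 626 reads per locus over both libraries and a range of 9 to 699455. Of these loci, 2312 (58.6%) were higher in library B and 1634 in library A, and without the 1059 loci whose read numbers matched those of another locus within 1% the counts were 1837 and 1050. Differences were mostly small: among the 3846 loci read in both libraries the median absolute log2 ratio was 0.57, and 74.7% differed by less than 1. At least 1 log2 separated the libraries at 693 loci higher in B and 380 higher in A. At least 2 log2 did so at 224 and 160. By coding-sequence model the split was 3463 higher in B and 2341 in A, and with the table's own totals it was 3268 and 2536. Centring the ratios on the table's median of -0.30 makes it 2902 and 2902 by construction. The authors' scaling cannot be checked here because models that missed their threshold are not in the table.

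**Figure D1:**
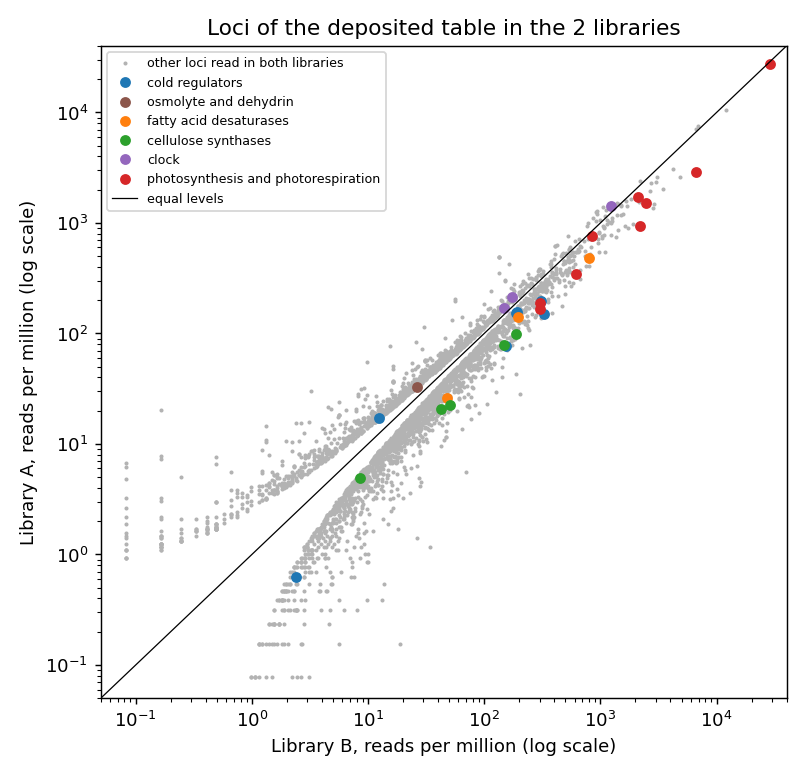
Level of each locus in library A (vertical axis) against library B (horizontal axis), in RPM on log scales, for the 3846 loci read in both libraries. The empty band along the line of equal levels holds the loci that missed the authors' threshold; the 5 cellulose synthases lie on the side of library B, and the photosynthesis and photorespiration genes were chosen after their values had been seen.

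Of 9 listed cellulose synthases, which make the cellulose of the cell wall, 5 were in the table, and these 5 were higher in library B under the authors' scaling, under centring and under the table's own totals. OsCESA6 (LOC_Os07g14850) had 22.4 RPM (reads scaled to the size of the library) in A and 50.3 in B, a log2 ratio of -1.17 (-1.37 to -0.96). OsCESA5 (LOC_Os03g62090) stood at -1.01 (-1.23 to -0.79) and OsCESA1 (LOC_Os05g08370) at -0.93 (-1.02 to -0.83), the latter from 1275 reads in A and 2290 in B. The ratio of OsCESA8 (LOC_Os07g10770) was -0.91 (-1.02 to -0.79). OsCESA2 (LOC_Os03g59340), with only 63 and 104 reads, had -0.80 (-1.28 to -0.34). OsCESA4, OsCESA7 and OsCESA9, which serve the secondary wall, were not in the table, nor was OsCESA3. The median of the 5 members, -0.93, lay at percentile 0.97 of random lists matched on level and at percentile 6.0 of unmatched lists. Family members are alike in sequence, and reads that fit several of them may have been assigned in a way not given in the sources used here.

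Among 13 regulators of the cold response, 7 were in the table, 6 of them higher in library B and 1 higher in A under the authors' scaling, against 4 and 3 after centring. The DREB1 genes, whose factors bind the promoter element of many cold-induced genes, had some of the larger ratios. OsDREB1A (LOC_Os09g35030) had 150.1 RPM in A and 328 in B, a log2 ratio of -1.13 (-1.21 to -1.05), and its neighbour OsDREB1B (LOC_Os09g35010) had 77.1 and 155, a ratio of -1.01 (-1.12 to -0.90). OsDREB1C (LOC_Os06g03670) rested on 8 and 29 reads and its ratio of -1.94 was imprecise (-3.28 to -0.77), at -1.06 with a pseudocount of 1 RPM. SNAC1 (LOC_Os03g60080), a NAC factor of stress responses, stood at -0.65 (-0.73 to -0.58). SNAC2 (LOC_Os01g66120) at -0.29 and the MYB-related OsMYBS3 (LOC_Os10g41200) at -0.28 were higher in B only under the authors' scaling and the table's totals, and turned to 0.011 and 0.024 when centred. COLD1 (LOC_Os04g51180), which encodes a membrane regulator of G-protein signalling tied to chilling tolerance, was the member higher in A, at 0.47 (0.16 to 0.77) from 222 and 152 reads, with an adjusted p of 0.0328 from edgeR in the authors' deposited table.

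The median of the 7 cold regulators was -0.65, at percentile 4.4 of level-matched random lists and percentile 13.2 of unmatched ones. OsDREB1G, OsICE1, OsICE2, OsMYB4, qLTG3-1 and bZIP73 were not in the table, and the reason for each is not known. OsDREB1A and OsDREB1B lie within a stretch of chromosome 9 in which 5 loci had reads in library B only. Of the 25 loci of that stretch read in both libraries, with OsDREB1A and OsDREB1B among them, 19 were higher in B (17 after centring) and 10 differed by at least 1 log2.

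The 3 listed genes of fatty acid desaturases, which add double bonds to membrane lipids, were in the table and higher in library B under each scaling. The plastid enzyme gene OsFAD7 (LOC_Os03g18070) was the most abundant, with 481 RPM in A and 794 in B and a log2 ratio of -0.72 (-0.77 to -0.68). OsFAD8 (LOC_Os07g49310) had a ratio of -0.87 (-1.07 to -0.67). OsFAD2 (LOC_Os02g48560), for the desaturase of the endoplasmic reticulum, had -0.49 (-0.58 to -0.40), which centring reduced to -0.18. The median of these 3 genes, -0.72, lay at percentile 4.6 of level-matched lists and 18.9 of unmatched lists.

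Of 4 listed clock genes 3 were in the table, each with a small positive ratio. OsCCA1 (LOC_Os08g06110), a MYB-type factor of the morning loop, had 1410.1 RPM in A and 1238 in B, a log2 ratio of 0.19 (0.16 to 0.22). OsPRR37 (LOC_Os07g49460) stood at 0.20 (0.10 to 0.29) and OsGI (LOC_Os01g08700) at 0.30 (0.22 to 0.38), the latter from the only model of that locus in the table. Both other scalings shift ratios towards A and so could not turn these 3. OsPRR1 was not in the table, and the list's median of 0.20 lay at percentile 88.3 of level-matched lists and 65.0 of unmatched lists. From the osmolyte and dehydrin list only OsP5CS1 (LOC_Os05g38150), for a proline synthesis enzyme, was in the table, higher in A at 0.32 (0.11 to 0.53) with 422 and 320 reads and an adjusted p of 0.0396 from edgeR in the authors' deposited table. OsTPP1, RAB21 and OsLEA3 were not. These ratios compare 2 libraries and have no replicate check, so the spread between plants of a genotype is unknown.

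**Figure D2:**
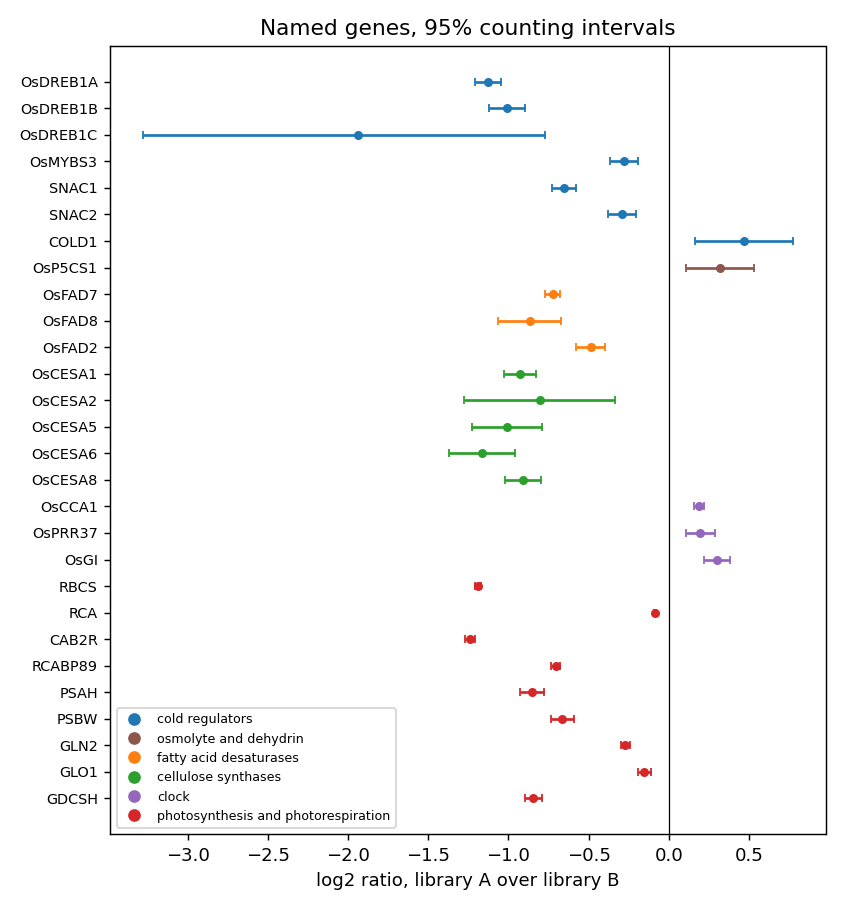
Log2 ratio of library A over library B (horizontal axis) for each named gene in the table; points are the ratios, bars the 95% counting intervals, which leave out the spread between plants. The 5 cellulose synthases and 3 desaturases shown lie below 0 under each scaling, the 3 clock genes shown lie above 0 (both other scalings shift ratios upwards and could not turn them), and SNAC2, OsMYBS3, RCA, GLN2 and GLO1 change sign when centred on the table's median; the genes from RBCS to GDCSH were chosen after their values had been seen.

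Reads in 1 library only were found at 54 loci for library A and 46 for library B. LOC_Os07g26000 on chromosome 7 had 1474 reads in A, or 114.7 RPM (109 to 120.7), and 0 in B. The lower limit of its level in A was at least 441-fold higher than the 0.247 RPM that 3 reads would give in B. LOC_Os07g22910 had 283 reads in A and 0 in B, at least 79.1-fold higher in A by the same measure. In library B, LOC_Os11g36200 had 123 reads, at least 36.0-fold higher than the floor of 0.234 RPM in A, and LOC_Os05g25080 had 116 reads, at least 33.7-fold higher. Most such loci were far weaker, with a median of 20.5 reads for those read in A and 19.0 for those read in B. By model there were 69 and 57, which became 132 and 102 when up to 3 reads were allowed in the other library.

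The chromosomes held unequal numbers of these loci. Chromosome 7 had 16 read in A only and 2 in B only, chromosome 9 had 2 and 12, and chromosome 11 had 10 and 12, whereas chromosome 3 with 485 loci in the table had 1. In all, 55 of the 100 loci lay in 9 runs. Library B alone had reads at the 6 such loci between locus numbers 25880 and 29540 of chromosome 9 and at the 5 between 32870 and 35540. Library A alone had reads at the 4 such loci between 8880 and 9700 of chromosome 1 and the 4 between 12240 and 13234 of chromosome 7. Runs with loci of either side lay on chromosomes 4, 6, 7 and 11. Locus numbers give order along a chromosome and not base pairs, and a value of 0 does not tell a missing gene from a silent one or from reads that did not align.

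**Figure D3:**
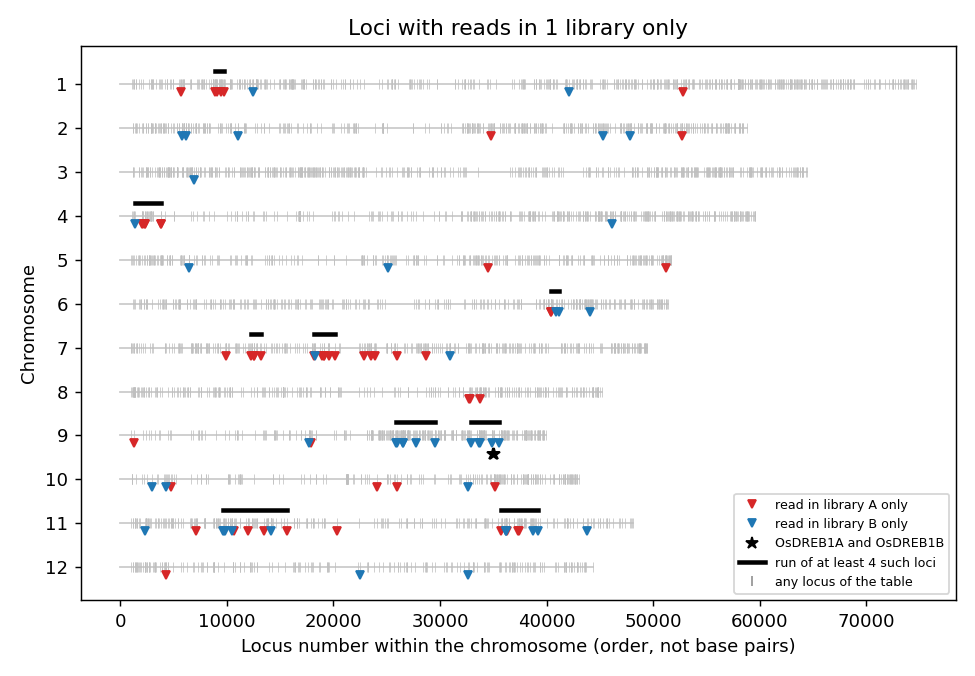
Loci of the table along the 12 chromosomes (vertical axis) by locus number (horizontal axis, order and not base pairs); triangles mark the 54 loci read in library A only and the 46 read in library B only, black bars the 9 runs. The stars on chromosome 9 mark OsDREB1A and OsDREB1B, inside a run of 5 loci read in library B only.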

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

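One model per locus, the removal of loci with matching read pairs, and the table's own totals for lists and genes were chosen after the data had been seen. Limits of 0.01 on p and 0.05 on adjusted p removed no model, so they test nothing. The counts of models higher in A (2341) and in B (3463) fell to 482 and 879 at an absolute log2 ratio of at least 1, to 199 and 264 at 2, and to 1228 and 1679 at or above the median level, because fewer models were counted; with 1 model per locus and no matching read pairs they were 1050 and 1837. B had more in each of these, but centring gave 2902 in both, by construction. Models read in A only (69) and B only (57) became 132 and 102 with up to 3 reads allowed in the other library. No list median changed sign under centring or the table's totals, which shift every ratio alike towards A and so could not turn the clock genes, COLD1 or OsP5CS1. Centred medians were -0.35 for cold regulators, -0.42 for desaturases, -0.62 for cellulose synthases, -0.40 for photosynthesis genes, 0.50 for clock genes and 0.62 for OsP5CS1, the only member of its list. With the table's totals they were -0.45, -0.52, -0.72, -0.51 and 0.40 for the first 5 in the same order. Of 28 named genes 5 changed sign when centred: OsMYBS3 to 0.024, SNAC2 to 0.011, RCA to 0.22, GLN2 to 0.033 and GLO1 to 0.15. RCA (0.12) and GLO1 (0.046) also did with the table's totals. Pseudocounts of 1 and 0.1 left all 28 within their counting intervals, which for OsDREB1C is wide: its ratio of -1.94 became -1.06 with a pseudocount of 1. The alternatives by transposon annotation and the keyword lists were not run. No paired analysis was possible because each genotype has 1 library. Depth limits OsDREB1C and OsCESA2 most, and genes that missed the authors' threshold have no value here.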

Other observations

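All tests below except 2, the one of like read numbers in neighbours and the one of sparse stretches without matching loci, were chosen after the results had been seen, as were the photosynthesis genes. Of 10 listed genes of photosynthesis and photorespiration 9 were in the table, all 9 higher in library B under the authors' scaling, 7 of 9 under the table's own totals and 6 of 9 after centring. CAB2R (LOC_Os01g41710), for a light-harvesting protein, had 936 RPM in A and 2209 in B, a log2 ratio of -1.24 (-1.27 to -1.21). RBCS (LOC_Os12g17600), for the small subunit of Rubisco, had 2886 and 6588, a ratio of -1.19 (-1.21 to -1.17). The photosystem genes PSAH (LOC_Os05g48630) and PSBW (LOC_Os01g56680) stood at -0.85 and -0.66, the light-harvesting gene RCABP89 (LOC_Os03g39610) at -0.71, and GDCSH (LOC_Os10g37180), for a part of glycine decarboxylase, at -0.85. Rubisco activase, RCA (LOC_Os11g47970), was the most abundant locus of the table, with 349194 and 350261 reads, and at -0.08 it hardly differed; RCA and GLO1 (LOC_Os03g57220, -0.15) turned positive under both other scalings and GLN2 (LOC_Os04g56400, -0.27) when centred. GLO5 was not in the table. The list's median of -0.71 lay at percentile 0.27 of level-matched lists and 8.6 of unmatched ones. Since the genes were picked from abundant loci already seen, this is no independent evidence. The counts by direction likewise hold for the picked genes alone, since the keyword list of photosynthesis genes was not run. Not every abundant locus was higher in B: LOC_Os01g51410, not on the list, had 96300 reads in A and 84335 in B, a ratio of 0.11. Its function was not looked up, so whether it belongs with the listed genes is not known here. RBCS and CAB2R belong to gene families whose copies may share reads, which was not tested for them; among loci with at least 100 reads in both libraries, 93 had the exact read numbers of another locus.

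Loci read in 1 library only lay near each other. Of the 100, 54 had a neighbour of the same side within 1000 locus numbers. In 10000 shuffles over all loci of the table the mean was 17.3 and the highest value 40, which argues against scattered placement among them. The shuffles did not match level, and these loci had medians of 20.5 (A) and 19.0 (B) reads against 626 for the table. The test thus cannot tell their nearness from nearness of weakly read loci in general. Inside the 9 runs, 43.9% of the 196 loci read in both libraries also differed by at least 1 log2, 38 higher in A and 48 in B. Outside the share was 24.3%, and 1000 rotations of the runs gave at most 35.7%. Loci inside the runs had lower levels, with a median of 16.3 RPM against 27.1 outside. Draws matched on level gave a mean of 34.2% and at most 40.8%, so part of the excess goes with level. Those draws took loci singly and lost any likeness between neighbours, while the rotations did not match level. Whether an excess beyond level remains is therefore not settled. Chromosome segments that differ between the genotypes are a candidate explanation of any such excess. Of the 54, 22.2% had a read number within 10% of a neighbour's, under the 25% set beforehand as speaking against reads shared between near-identical neighbours. That explanation is left open because the exact binomial interval (12 to 35.6%) reaches above 25%, a requirement added after the value had been seen. Reads that did not align, missing genes and silent genes all give a value of 0 and were not tested against each other. Unequal alignment could also shift the ratios of loci read in both libraries, inside the runs or outside, and was not tested.

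Many loci held nearly the same pair of read numbers. Among 2705 loci with at least 100 reads in both libraries, 93 in 41 groups, 33 of them across chromosomes, had exactly the read numbers of another locus, against a mean of 34.3 and at most 60.0 when each number was moved at random by up to 2%. In addition, 128 loci on all 12 chromosomes had 1221 to 1445 reads and a log2 ratio of 0.40 to 0.50, while the neighbouring classes of ratio held 44 and 8. That class held 71.1% of the 180 loci, with an exact binomial interval of 56.7 to 83.1% once widened because it was picked as the fullest of 517 classes. Counting error of independent reads allows at most 50.5% for any mixture of ratios, which argues against independent genes of like level, on classes that were themselves set after the distribution had been seen. Reads counted at several copies, as of a repeated sequence, may account for both, and such loci are not separate measurements. An earlier form of the second test, which redrew the reads of those loci, was dropped because it added counting error to values that already held it.

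In stretches of 5000 locus numbers with fewer loci than the median of 29, 52.6% of 1182 loci were higher in library A, against 36.6% of 2764 in the other stretches, a difference of 16.0 percentage points. Without the 1059 loci that matched another within 1% in both read numbers the shares were 47.4% and 32.2%, a difference of 15.2 points. It kept 94.9% of its size, above the 75% set beforehand as speaking against repeated read pairs. The binomial SE of 2.04 points takes loci as independent, while the contrast is between 64 and 66 stretches. It may be too small, so no conclusion is drawn beyond the removed loci. About 806 loci also matched when reads were redrawn around the observed numbers. Those redraws keep the repeated pairs and add counting error again, so they give no rate of matches by chance. Copies with under 100 reads or with less similar numbers were not removed and stay open. The share higher in A also differed by chromosome, from 33.2% on chromosome 3 to 56.4% on chromosome 12. The stretches were not compared within chromosomes, so their difference may be partly one between chromosomes. No biological explanation of the difference between stretches was tested.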
